A study of Mus musculus with 3 samples.

How the data were processed

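Gene expression was measured in 3 samples of mouse neural retina at postnatal day 7, each a pool of retinas from 3 to 4 wild-type animals, per the labels. The values were the authors' processed intensity per probe set on a linear scale, from 0.1 to 55245.8. The software that made the intensity values deposited by the authors, its version and any background correction are not given in the sources used here. The deposited intensities had been scaled per array: their mean without the lowest and highest 2% was 500.2, 500.3 and 500.2 in pools 1, 2 and 3. Their medians were 235.1, 207.7 and 235.9. Detection calls were not used here. The array type, MG-U74Av2, was read from the sample titles. Nothing says more about the replicates than that each sample pooled several animals, so the p-values measure the spread between these samples, part of which may be technical.

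Gene names came from the platform annotation supplied with the series, with symbols updated by gene ID through a RefSeq table of assembly GRCm38.p6, from which names alone were taken. Of 12422 probe sets that were not controls, 10833 had 1 gene, 396 had several and 1193 were unnamed here, and 10817 of the first kind had a symbol found by gene ID. Probe sets with several genes were given no name. Each of the 8251 genes was represented by 1 probe set: one whose name carries no letter suffix before any other, then the one with the highest mean. For 2073 genes there was more than 1, and they could disagree, as they did for Crybb2 and Actb.

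Each array was divided by its median over the non-control probe sets and multiplied by the mean of the 3 medians (factors 0.962, 1.09 and 0.959, a log2 shift of -0.06, 0.12 and -0.06), then floored at the 20th percentile of all scaled values, 42.2, and put on the log2 scale. All intensities and deviations reported are on this scaled basis. The background bar was each array's 90th percentile over 53 measured genes of unrelated tissues (such as liver, pancreas, pituitary and testis), and 53.0%, 54.4% and 50.8% of genes passed it in pools 1, 2 and 3. The signal taken by the 100 brightest probe sets was 16.3%, 19.8% and 20.7%.

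Excess spread was tested on 6211 probe sets, the 50% with the highest mean log2 value. The variance of each over the 3 arrays (2 residual degrees of freedom) was set against the prior variance that limma's squeezeVar, with its robust option and the mean level as covariate, estimated from all probe sets. The upper-tail p-values, taken for every probe set at the highest prior degrees of freedom that squeezeVar gave, were adjusted with the Benjamini-Hochberg method at 0.05. The test asks if a probe set varied more than others of its brightness and uses no grouping of the arrays. Its adjusted values are called limma adjusted p below. On data simulated from the 6211 real probe sets with 200 of them changed in 1 array, over 10 runs, 8.16% of 2-fold, 73.8% of 4-fold and 97.5% of 8-fold changes were recovered, and 1.17% of calls were false. Most changes near 2-fold would thus be missed. The simulated noise was normal, at the estimated prior spread and without a floor. The share of false calls in the real data can therefore be higher and was not measured.

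There were 21 gene lists for retinal cell types (rods, cones, bipolar cells, Müller glia, amacrine and horizontal cells, ganglion cells), for cell cycle, progenitors, synapse, oxidative phosphorylation, ribosomal proteins, clock, immediate early and stress genes and sex-linked genes, and for tissues that dissection could carry over (lens, pigment epithelium, blood, vessels, microglia and immune cells, astrocytes and oligodendrocytes, muscle and connective tissue), plus the list for background. For each list the members above background in all pools were counted. For each list with at least 3 such members and each array, the median log2 deviation from the gene's mean over the arrays was given with its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. Tested on simulated lists of 6 genes among 4126 real ones, the share of 100 runs outside the central 95% was 86.0% for a log2 shift of 0.5 and 2.0% for no shift. For 15 genes these were 99.0% and 8.0%. Enrichment of lists among genes with excess spread used a two-sided Fisher's exact test over the 4698 genes whose chosen probe set was tested, of which 49 had excess spread, with Benjamini-Hochberg adjustment over the lists. RNA quality was described by the 3' to 5' ratios of control transcripts.

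The lists, main tests, alternatives and the rule for named genes were set before the data were examined. Not part of that plan were the adjustment over a list alone and the count of lens probe sets among the lowest p. The same holds, limma's test aside, for the tests under other observations. The rule took Rp1; from each list, in its written order, the first 4 members above background; the 10 genes with the largest SD among those with excess spread; and, for a list outside its random range, the 3 members that deviated most. The text gives a selection of them. Other genes it names, control transcripts aside, were not set by this rule and were chosen after their values were seen, also where this is not said. Alternatives were no scaling, quantile normalisation, a floor at the 5th percentile, a pseudocount in place of the floor, no filter or a stricter filter (brightest 25%) on dim probe sets, the 75th percentile or the array median as background bar, the mean of all probe sets of a gene, other variance models, a 2-fold limit in place of the test, the middle control probe set, and leaving out each array. Group comparisons and correlations across samples were not made, because there was 1 group of 3 samples. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.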

Results

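The data described the transcriptome of the normal mouse retina at postnatal day 7 (P7), an age at which photoreceptors are still maturing. Total RNA from 3 samples was hybridised to Affymetrix MG-U74Av2 oligonucleotide arrays, on which each gene is read by 1 or more probe sets. Each sample was a pool of neural retinas from 3 to 4 wild-type littermates of mice lacking Rp1, a photoreceptor gene mutated in a form of retinitis pigmentosa, on a mixed 129/SvEv and C57BL/6 background. The retinas were collected between 1 and 2 pm. The labels placed all 3 samples in 1 group, so no groups were compared, and the questions open to the data were which genes had signal and how far the pools differed from each other. The pools are called pool 1, pool 2 and pool 3, the numbers being names only. Rp1 itself was not analysed here. The table held 12488 probe sets, of which 12422 were analysed after 66 control probe sets were left out, and the number of arrays limited the precision of every value.

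Genes of rod photoreceptors, the cells of dim-light vision, had signal above background in all 3 pools for 15 of the 17 measured members of the rod list. Sag, which encodes rod arrestin, had an intensity of 13718 ± 1455 (mean ± SD, n = 3 pools, as for every such value below). Pde6b and Pde6g, subunits of the rod phosphodiesterase, were at 6026 ± 980 and 7318 ± 862. Nrl, the transcription factor that sets rod fate, was at 627 ± 145. In the cone list 4 of 8 measured genes were above background, a share close to the 47% of all genes. Among them were the short-wavelength opsin gene Opn1sw at 1649 ± 379 and the cone transducin gene Gnat2 at 902 ± 32.1.

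Lists of the other neurons and the glia of the retina had members above background too. Of all genes 47% were above it. The shares of the bipolar list and the amacrine and horizontal cell list were little above this and do not alone show those cells. In the bipolar cell list 4 of 7 measured genes were above background, and Prkca, Pcp2 and Grik1 were not. Among the 4 were Neurod4, a transcription factor gene of developing interneurons, at 5088 ± 258, and Trpm1, the channel of ON bipolar cells, at 328 ± 46.6. In pool 1 Trpm1 was at 286, close to the bar of 272. The amacrine and horizontal cell list had 9 of 16, with Gad1, which encodes a GABA-synthesising enzyme, at 2129 ± 200 and Pax6 at 2282 ± 310. The ganglion cell list had 11 of 12, with the neurofilament gene Nefl at 567 ± 159 and the surface antigen gene Thy1 at 954 ± 215. The Müller glia list had 10 of 12, with Rlbp1, the retinaldehyde-binding protein gene, at 2900 ± 419 and the glutamine synthetase gene Glul at 412 ± 26.0. Synaptic genes were above background for 9 of 12 measured members, with Snap25 at 6750 ± 1283 and Vamp2 at 3831 ± 140.

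Part of the genes of dividing cells and most progenitor genes were above background. The share of the cell cycle list was below the 47% of all genes and does not alone show dividing cells. The cell cycle list had 11 of 27 measured genes, among them the cyclin genes Ccnd1 at 1946 ± 288, Ccnb2 at 580 ± 62.0 and Ccna2 at 678 ± 41.0, and the replication clamp gene Pcna at 955 ± 137, while Mki67, Top2a, Cdk1, Aurka, Aurkb, Birc5 and Rrm2 were not above background in all 3 pools. The retinal progenitor list had 11 of 15, with the Notch pathway genes Notch1 at 1282 ± 473, Hes1 at 492 ± 84.8 and Hes5 at 320 ± 52.0. Hes1 was on the Müller glia list too. Among lists of general cell function, 17 of 25 measured oxidative phosphorylation genes, 10 of 16 ribosomal protein genes, 11 of 21 immediate early and stress genes and 7 of 13 clock genes were above background. For the immediate early and stress list and the clock list these shares were close to the 47% of all genes. Arntl, a core activator of the circadian clock, was at 1895 ± 306, and Egr1, an activity-induced transcription factor gene, at 380 ± 98.5.

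Markers of neighbouring tissues were mostly not above background, with the lens as the exception. The pigment epithelium and pigment cell list had 1 of 10 measured genes above background (Dct, 384 ± 76.6), the red blood cell list 1 of 9 (the globin gene Hba-a1, 4147 ± 2216), the astrocyte and oligodendrocyte list 1 of 9 (Mbp, 426 ± 43.5), and the extraocular muscle and connective tissue list 2 of 19 (Col1a1, 448 ± 107, and Actc1, 768 ± 260). Vascular genes were above background for 5 of 15 members, with the endothelial receptor gene Kdr at 1216 ± 75.6, and microglia and immune genes for 5 of 16, with C1qc at 569 ± 158 and Cx3cr1 at 446 ± 117. The lens list had 6 of 12 by the 1 probe set chosen per gene, and other probe sets of Cryab, Crygd and Cryge were also above background in all 3 pools. Among the 4 measured sex-linked genes the Y-linked gene Eif2s3y was above background at 728 ± 139, from a probe set whose type can be shared between related transcripts.

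**Figure D1:**
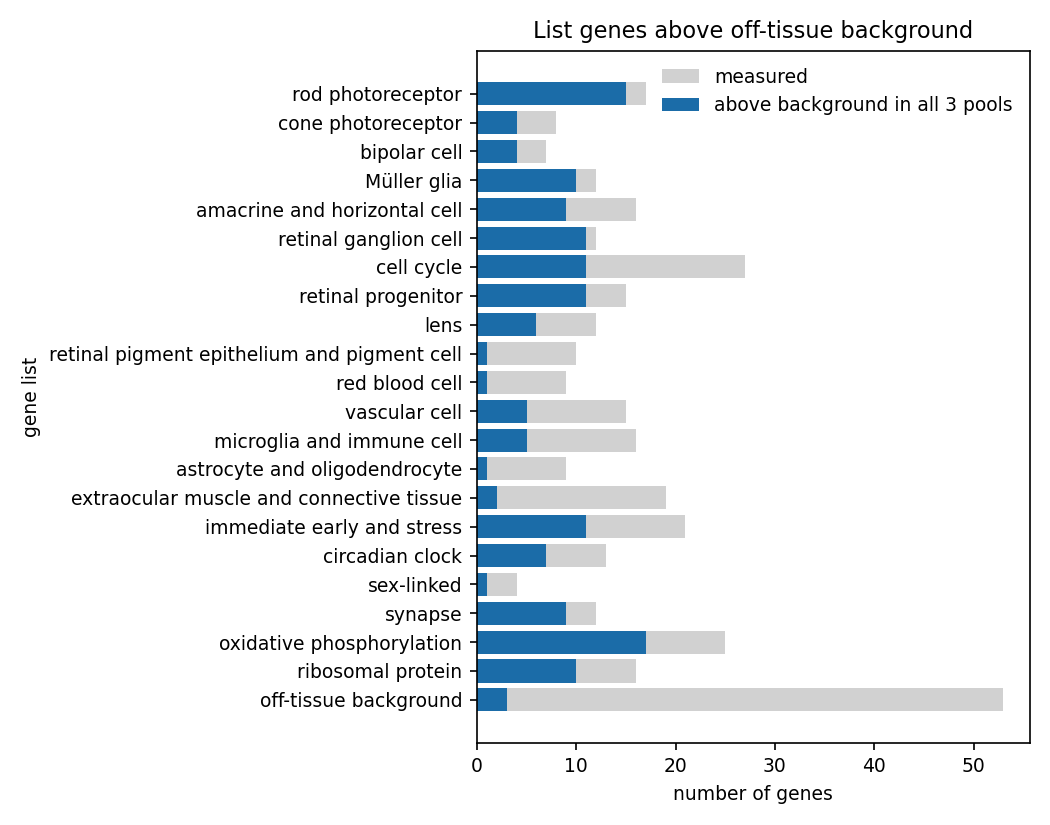
Number of genes (horizontal axis) in each gene list (vertical axis) that were measured (full bar) and that lay above the off-tissue background in all 3 pools (dark part). The rod list had 15 of 17 measured genes above background and the off-tissue list 3 of 53.

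Background was set by genes of tissues unrelated to the retina: a gene counted as above background when its intensity passed the 90th percentile of these genes, 272, 253 and 287 in pools 1, 2 and 3. Of the 53 such genes measured, Krt10, Ctrb1 and Lhb were above it in all 3 pools. In all, 148 of the 292 measured list genes passed, as did 3881 of all 8251 genes (47.0%). A value below the bar does not show that a gene was silent. The chosen probe sets of the ribosomal protein genes Rpl7, Rps14 and Rps15 had means of 42.2, 43.4 and 55.4. With the 75th percentile as the bar, 8 lists had over 1.5 times as many genes above background: cell cycle 17, immediate early and stress 17, vascular 9, microglia and immune 8, muscle and connective tissue 4, pigment epithelium and pigment cell 3, sex-linked 3 and red blood cell 2.

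Lens genes differed between the pools, and pool 1 was the low one. Cryaa, which encodes the alpha-A crystallin of lens fibres, had intensities of 7413, 38200 and 39990 in pools 1, 2 and 3, so that pools 2 and 3 were 5.27-fold above pool 1. Its limma adjusted p, 1.32e-06, and those below are for the spread over the 3 pools and not for the fold. Crygs, a gamma-type crystallin gene, was at 3064, 19639 and 15282 (5.65-fold, limma adjusted p = 1.03e-07), and Crygc at 3001, 20351 and 21616 (6.99-fold, limma adjusted p = 2.21e-09). Crygb, Cryba1 and Crybb2 were 4.79-fold, 3.73-fold and 4.16-fold higher in pools 2 and 3, and outside the crystallin family Mip, the lens fibre water channel gene, and Bfsp1, a lens fibre intermediate filament gene, were at least 2.41-fold and 2.87-fold higher, bounds set by the background bar because their pool 1 values of 193 and 212 lay below it. All 6 lens genes above background in all 3 pools were lowest in pool 1. Gja3 was below background in every pool. Gamma crystallin genes are close paralogs whose probes can cross-hybridise, so values of single members are uncertain. A further probe set of Crybb2 (861, 735 and 789) did not follow. One of Crygb (328, 391 and 1106) was lowest in pool 1 too, but stood well above it in pool 3 only. Probe sets that may be shared between crystallin genes followed for Crygd (8414, 38271 and 43189), Cryge (7456, 33853 and 39207) and Cryab (572, 1550 and 2021).

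All 8 lens genes whose chosen probe set was tested had a spread between pools beyond that of probe sets of the same brightness. All 8 also had it when adjusted over the list alone, an adjustment that was not planned. Over all probe sets, 13 of 14 tested from the lens list had it, from 11 genes. The lens list was the single list enriched among genes with excess spread (two-sided Fisher's exact test, adjusted p = 1.62e-15 over the lists). That test treats genes as independent, whereas the lens genes moved together in 1 low pool, so its p does not measure evidence across pools. The lens count was 4 without scaling between arrays and 4 after quantile normalisation, both with the list still enriched, and 0 when dim probe sets were kept in the test. It rested on pool 1, since without that pool no lens gene was called.

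**Figure D2:**
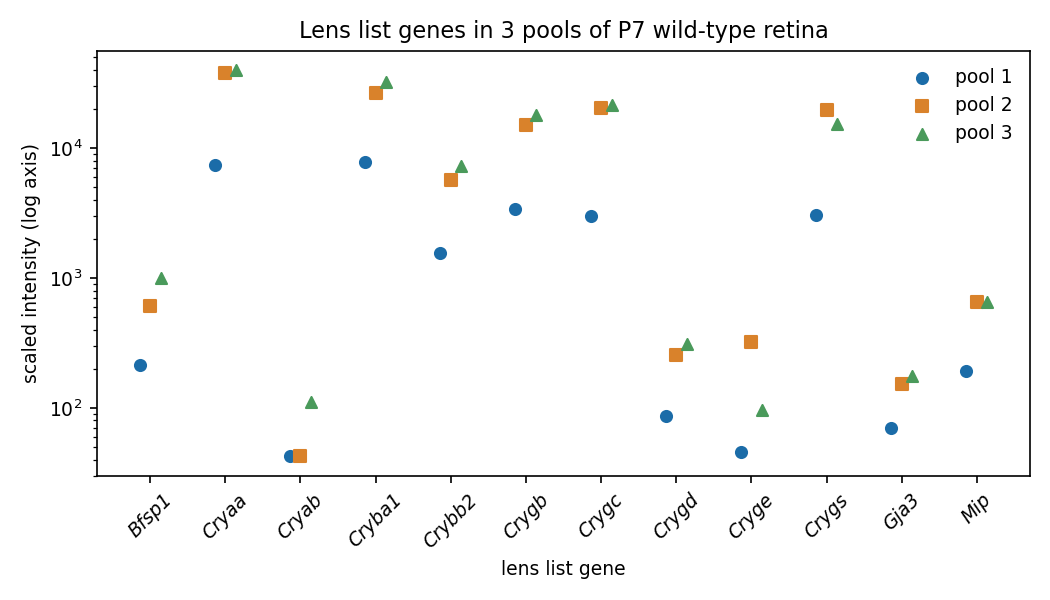
Scaled intensity (vertical log axis) of the 12 measured lens list genes (horizontal axis) in each pool, 1 symbol per pool and no error bars. The 6 genes above background in all pools were lowest in pool 1, as for Cryaa at 7413 against 38200 and 39990, and points below the bars of 272, 253 and 287 in pools 1, 2 and 3 have no order.

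Outside the lens, the genes with the widest spread by their chosen probe set belonged to no common list. Txnl4a, a spliceosome component gene, was at 652, 1583 and 186 in pools 1, 2 and 3 (limma adjusted p = 1.14e-07), and Limk1, which encodes a kinase acting on cofilin, at 1057, 1737 and 263 (limma adjusted p = 2.64e-07). Another probe set of Limk1 did not follow, with a log2 deviation of -0.04 in pool 3 against -1.58 for the called one. Acy1, an aminoacylase gene, was at 403, 481 and 67.6, and 1110032A03Rik at 531, 284 and 79.3, both lowest in pool 3. The called probe sets of Limk1 and 1110032A03Rik are of a type made under relaxed selection rules. Cep250, a centrosomal protein gene, was lowest in pool 2 (575, 73.1 and 342). Cela1, an elastase gene of the off-tissue list, and Serpina3n, a serine protease inhibitor gene, were lowest in pool 1, at 73.0, 427 and 695 and at 92.9, 255 and 634. In the rod list, 2 of 17 genes tested by their chosen probe set had excess spread, or 3 when adjusted over the list alone, and the list was not enriched (Fisher's exact test, adjusted p = 0.138). These genes, chosen after their values were seen, were the rod transducin gene Gnat1 at 219, 699 and 680, the disc protein gene Prph2 at 1261, 981 and 3901, and, over the list alone, Gnb1 at 10928, 14984 and 5848. Over all probe sets, another probe set of Gnb1 (3239, 3783 and 934) was called too. So was one of the rod list gene Rom1 (2128, 686 and 819), whose chosen probe set was at 2678, 3239 and 2613. One of 14 cell cycle genes tested, Rrm1, had excess spread (555, 489 and 116). Apart from those of Prph2, Gnb1 and Rom1, the lowest values in this paragraph lay below the background bar of their pool and are not measured levels. Without pool 2 all 9 calls were of lens list probe sets, so no gene of this paragraph was called. Without pool 3 none of Txnl4a, Limk1, Acy1, 1110032A03Rik, Cep250, Cela1 and Serpina3n was called. Of these, Txnl4a and Limk1 alone stayed called without pool 1. A gene not called had either lost its call or fallen below the brightness limit, so that it was not tested.

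Of 6211 probe sets in the brighter part of the array, 83 had excess spread at a limma adjusted p below 0.05, and 420 at an unadjusted p below 0.05. Pool 1 stood apart as the low one in 40 of them, 12 of these from lens list genes, and pool 3 in 26. The count depended on the scaling: it was 6 without scaling and 6 after quantile normalisation, and all 6 were lens crystallin probe sets in both cases. It was 30, 9 and 23 without pools 1, 2 and 3 in turn.

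Lists of retinal cell types lay within the range of random lists of the same size and level in each pool, with 1 exception under an alternative: with the mean of all probe sets of a gene, the rod list was at -0.21 in pool 3, at the 0.5th percentile. The rod list had median log2 deviations of -0.15, 0.20 and -0.12 in pools 1, 2 and 3, against random ranges of -0.23 to 0.02, 0.09 to 0.28 and -0.17 to 0.02. The ganglion cell list was at 0.10, 0.10 and -0.07, the Müller glia list at -0.05, 0.24 and -0.14, the cell cycle list at -0.04, 0.08 and -0.08, and the progenitor list at 0.00, 0.14 and 0.02, all inside their ranges. The lens list was at -1.55 in pool 1, with 6 of 6 members lower and below all 10000 random lists, and at 0.70 and 0.85 in pools 2 and 3, above all of them. Without pool 1 the deviations in pools 2 and 3 were -0.09 and 0.09. These were small but still outside the random range, at the 0.11th and 99.89th percentiles. The microglia and immune list was at 0.21 in pool 3, at the 98.6th percentile, with 4 of 5 members higher, among them Cx3cr1 (402, 357 and 578), C1qc (387, 667 and 654) and Cd14 (581, 351 and 562). Of the 48 list and pool pairs, 4 lay outside the central 95% of random lists, where chance gives 2.4. The microglia deviation was -0.01 without pool 1 and 0.09 without pool 2.

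**Figure D3:**
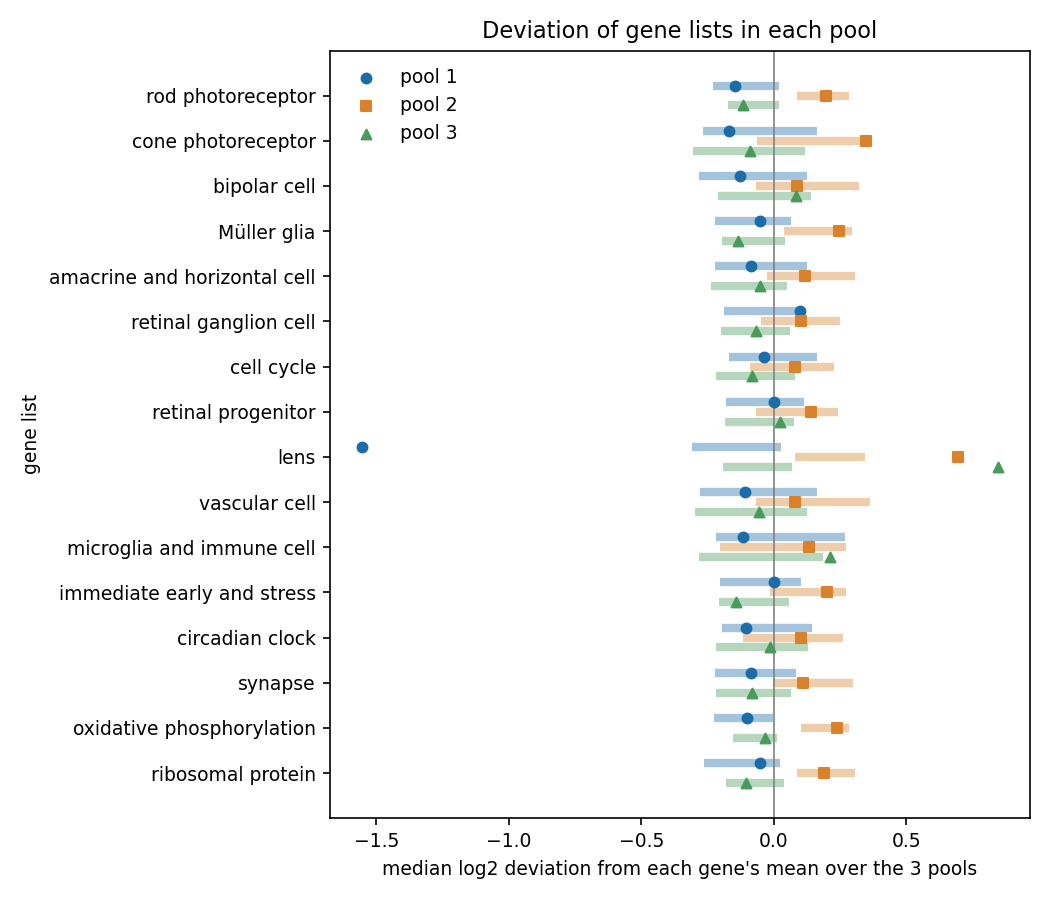
Median log2 deviation of list genes from their mean over the 3 pools (horizontal axis) for the 16 gene lists with at least 3 members above background (vertical axis), 1 symbol per pool, with pale bars for the central 95% of 10000 random lists matched on level. The lens list lies outside its bars in each pool, at -1.55, 0.70 and 0.85.

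The control transcripts on the array gave 3' to 5' ratios, a measure of RNA length and labelling, that were highest in pool 1. For Actb, the beta-actin gene, the ratio was 1.81, 1.27 and 1.30 in pools 1, 2 and 3, and for Gapdh 0.874, 0.788 and 0.812. The 5' probe set of Tfrc, the transferrin receptor gene, was below background in every pool, so its ratio gives no order. Pool 1 was thus also the pool with the lowest lens values. The 3' control probe set of Actb was at 16322, 30166 and 26439, whereas other Actb probe sets were at 5137, 2685 and 3088 and at 7611, 7103 and 6856. Bacterial transcripts added as hybridisation controls (9 probe sets) had median log2 deviations of -0.29, -0.05 and 0.33.

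Apart from such genes the 3 pools were close to each other. The median probe set had an SD of 0.26 on the log2 scale, and 96.3%, 95.3% and 96.3% of the 6211 probe sets were within 2-fold between pools 1 and 2, 1 and 3, and 2 and 3. Across these probe sets, which are not independent replicates, Pearson's r was 0.937, 0.921 and 0.940 and Spearman's rho 0.924, 0.903 and 0.922. The median absolute log2 difference was 0.31, 0.28 and 0.31. A range above 2-fold was seen for 536 probe sets (8.63%). Pairs of pools had 11 or 12 exactly equal intensities as deposited, before scaling and flooring, among the 12488 probe sets, so no array was present more than once.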

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

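All alternatives here were planned, and their effects were as follows. The number of probe sets with excess spread moved from 83 to 6 without scaling (313 at an unadjusted p below 0.05), 6 after quantile normalisation (340), 0 without the filter on dim probe sets (141), 27 in the brightest 25% of probe sets and 38 without limma's robust option, and 536 had a range above 2-fold. Leaving out each pool gave 9 to 30. It was 82 to 84 with the other floor, the pseudocount and 1 prior variance. In a count that was not planned, the 13 lens list probe sets among the 83 were also among the 83 with the lowest p under no scaling, quantile normalisation and no filter. The number of lens genes with excess spread was 4 without scaling, 4 after quantile normalisation and 0 without the filter, and 0 to 6 when each pool was left out, being 0 without pool 1. The number of enriched lists was 1 except for 0 without the filter and 0 to 1 when each pool was left out. Of 13 named genes with excess spread, 9 were no longer called without scaling, 9 after quantile normalisation, 3 without limma's robust option and all 13 without the filter. Without pools 1, 2 and 3 in turn, 2, 6 and 3 of the 13 stayed called. Another 8, 5 and 7 were tested and lost the call, and the others fell below the brightness limit and were not tested. The prior degrees of freedom, which set the weight of the common variance in limma's test, were 279, but 0.851 without the filter, 8.56 without scaling and 8.66 after quantile normalisation.

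The lens deviation in pool 1 stayed between -1.55 and -1.12 under the alternatives. That of pool 2 (0.70) ranged from -0.086 without pool 1, where the comparison is with pool 3 alone, to 1.124 without pool 3, and that of pool 3 (0.85) from 0.086 without pool 1 to 1.177 without pool 2. The microglia deviation in pool 3 (0.21) was 0 without the filter, and -0.013 without pool 1 to 0.09 without pool 2, and the cause was not tested. Some lists within their random range left it: rods in pool 3 at -0.209 with the mean of all probe sets of a gene, synaptic genes in pool 2 at -0.012 in the brightest 25%, and, without the filter, microglia in pool 2 at 0.161 and immediate early genes in pool 1 at 0.124. The mean of the 3 median absolute log2 differences between pools, 0.30, was 0.271 without scaling, 0.265 after quantile normalisation, 0.278 with a pseudocount, 0.273 in the brightest 25%, and 0.279 to 0.306 when each pool was left out. The number of list genes above background was 147 to 196. With the middle control probe set in place of the 5' one, the Gapdh ratios were 1.02, 0.891 and 1.00 in pools 1, 2 and 3, and those of Tfrc 7.77, 4.80 and 6.24, which have no order since that probe set was below background in every pool. Signal over background is a limit too: a gene below the bar in a pool has only a bound there, and 16 of 27 cell cycle genes were below it in at least 1 pool. No paired analysis was possible because there was 1 group.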

Other observations

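Apart from limma's test over all probe sets and its alternatives, which were planned, the tests in this part were chosen after the results were seen. So were the genes it names outside the gene lists. The alpha-globin gene Hba-a1 was at 2914, 6705 and 2821 in pools 1, 2 and 3 (limma adjusted p = 0.107), the beta-globin gene Hbb-b2 at 650, 1016 and 440 (limma adjusted p = 0.465) and the globin pseudogene Hba-ps3 at 435, 444 and 329 (limma adjusted p = 0.992), so none passed the threshold over all probe sets. The embryonic globin genes Hba-x and Hbb-y were below background in every pool. Pmel, a melanosome gene, was at 145, 412 and 293 and did not pass either (limma adjusted p = 0.554). Hba-a1 and Pmel passed when adjusted over the list alone, but with 1 and 2 genes tested in their lists this is little or no adjustment. Several other genes with excess spread were lowest in pool 1 along with the lens genes, among them Nupr1 (258, 1005 and 951), Timp2 (145, 654 and 503) and Tgfb1i1 (156, 646 and 865), whose values in pool 1 were below the background bar of 272.

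Lens genes were lower in pool 1 than in the other pools, and Mip and Bfsp1, 2 of the 3 measured lens genes outside the crystallin family, had excess spread with pool 1 lowest, which argues against a change of crystallin transcripts alone. Their log2 SDs, 1.02 and 1.14, were about as large without scaling (0.97 and 1.13) and after quantile normalisation (1.01 and 1.18), and larger without pool 2 (1.24 and 1.59), but limma's prior degrees of freedom fell from 279 to 8.56, 8.66 and 7.96 and the calls ended (adjusted p 0.481 and 0.282, 0.332 and 0.197, and 0.639 and 0.346), as they did without the filter (0.266 for both), for Mip without the robust option (0.105), for Bfsp1 without pool 3 (0.166) and, with the low pool gone, without pool 1 (0.997 and 0.983). An effect of brightness on the array is argued against, at the levels they cover, by the 200 brightest other genes. Their median log2 deviation in pool 1 was -0.15 (SD 0.17) against -1.55 for the lens list. Control probe sets were not among them, and those of Actb and Gapdh were lower in pool 1, whereas other Actb probe sets were not. The 5' ones were at 9015, 23731 and 20325 for Actb and at 23072, 33908 and 30690 for Gapdh in pools 1, 2 and 3. An effect at the highest intensities is therefore not excluded. Lens tissue left on the dissected retinas in unequal amounts may be the source: with pool 1 put at its background bar, Mip and Bfsp1 were higher in pools 2 and 3 by a median of at least 1.39 on the log2 scale, and the 6 crystallins above background by 2.33. None of the lens genes was on another list, although some crystallins are also made in retina, and a lens-wide difference within the retina and an effect of the RNA quality of pool 1 were not tested and stay open.

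Outside the lens list 70 probe sets had excess spread. For the 28 of them lowest in pool 1 and the 26 lowest in pool 3, other probe sets of the same gene, where tested, deviated less than the called one. Called probe sets were picked for a large deviation, so a smaller one in the others would be seen under any cause and does not alone show noise. For lens genes 3 of 4 comparisons went in the same direction with a median share of 0.67. They came from Crybb2, which went the other way, Crygb, and 2 Cryge probe sets that were each set against the other. These are too few for a contrast with genes outside the lens list. For genes lowest in pool 3, the 10 other probe sets tested had a median deviation in that pool of 0.02 of the called one (7 of 10 in its direction, exact sign test p = 0.344). For genes lowest in pool 1 this share was 0.09 (9 of 13, exact sign test p = 0.267). Several other probe sets could come from 1 gene, as 3 did for Bag6, so the sign tests do not count independent genes. Noise of single probe sets is a candidate explanation for both that these comparisons cannot decide. Some of the other probe sets did follow in part, as in pool 3 for Gnb1 (log2 deviations of -1.27 for the called probe set, -0.50 and -0.75), Acaa1b (-1.52, -0.77) and Fbxw4 (-1.01, -0.39), and in pool 1 for 2 of the 3 others of Bag6 (-1.66, -0.57 and -0.51). Probe sets of the type that Affymetrix marks as made under relaxed selection rules were 24.3% of the 70 and 4.15% of those not called (Fisher's exact test p = 4.63e-09).

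Xist, the RNA that coats the inactive X chromosome of female cells, was at 804 in pool 1 and at 55.3 and 59.4 in pools 2 and 3, the latter below background, so that pool 1 was at least 2.98-fold above the other pools, taken at the mean of their bars on the log2 scale. Noise of a dim probe set is argued against, since 0% of the 6701 other probe sets below background in 2 or more pools reached as far above it in the remaining one. Pools of different sex makeup may be the source, but the Y-linked gene Eif2s3y was 0.22 higher in pool 1 than in the others on the log2 scale, not lower. That probe set may also detect the X-linked copy, and the Y-linked genes Kdm5d (134, 124 and 149) and Uty (142, 171 and 226) were not above background, so the makeup of the pools cannot be told from these arrays.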
